A study of Mus musculus with 8 samples.

How the data were processed

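Poly(A) RNA from the gastrocnemius muscle of 16-week-old C57BL/6 mice was sequenced in 8 libraries, 4 from control mice carrying a floxed glucocorticoid receptor gene (Nr3c1) and 4 from mice in which an inducible Cre recombinase (Cre-ERT2) under the human skeletal actin promoter was used to delete the receptor in myofibres. Per the labels' protocols, libraries were made from 700 ng of total RNA with a stranded dUTP kit. Per the submitters' processing notes and the series' design text, the authors converted base calls with bcl2fastq 2.17.1.14, aligned reads to the mm10 mouse genome with TopHat version 2, counted reads per gene with HOMER and tested genes with edgeR and DESeq. The annotation release behind the counts and whether HOMER counted by strand are not given in the sources used here.

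The authors deposited raw read counts per Ensembl gene for 48709 genes, with no normalisation. The columns carry numbers that occur in no label, so each was assigned to its group by its name. The libraries are called here by letters in the order of the columns: A to D are control and E to H are labelled knockout. No label ties a replicate number to a column. The order of the columns and that of the labels' titles both depart from sequence in the last pair of the knockout group, but a mapping from order alone was not used. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries. Totals ran from 36680510 to 52200305 counts. The closest pair of libraries within a group differed by a chi-square of 13.12 per degree of freedom over genes with at least 10 counts in the pair, so no library was a copy of another within sampling noise.

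Genes were kept with edgeR's filterByExpr at its defaults (a count of about 10 in the smaller group and a total of 15), which left 14712 genes. Libraries were scaled by TMM, and the groups were compared with edgeR's robust quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with no covariate. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The log2 fold change is always the libraries labelled knockout over control, its SE is the absolute log2 fold change divided by the square root of the F statistic, and expression is given as TMM-scaled CPM (library-scaled counts), computed from the deposited counts. Log2 CPM used a prior count of 2. CPM of Nr3c1 and Fkbp5 was also compared by a two-sided exact permutation test over the 70 arrangements of the libraries. On simulated counts for this comparison with 14522 genes, the test recovered 94% of genes set at a log2 fold change of -2, 76% at -1, 92% at 1 and 98% at 2, with 15 false calls (7.69% of calls). The simulation held no GC trend and set no change smaller than 1 log2 unit, so these rates do not cover either.

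A total of 35 gene lists, 24 of pathways or processes and 11 of cell type markers, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with an estimated correlation and fry beside it. A further list of sex-linked genes was read as values, in CPM of the library total without TMM. The named genes were also fixed by rule before the data were examined: Nr3c1; the 12 highest and 12 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the groups; the 5 smallest p-values in each direction, in both cases skipping predicted and unnamed genes; and, from each list, up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. The rule took 125 genes, of which the report gives a part. Genes named outside the rule are marked as chosen after their values were seen.

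Gene coordinates, gene types and the GC content of the longest transcript came from GENCODE release M21 on GRCm38, the same assembly as mm10. Of the tested genes, 14687 had a record, and the 25 without one were not corrected when the GC trend was removed. The alternatives planned before the data were examined were DESeq2 size factors, upper-quartile scaling, library size alone, the 20 most abundant genes left out, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), counts thinned to the smallest library, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, an added minimum log2 fold change of 1, and each library left out in turn. A fit with the replicate number as a block was also planned and was not made, since no label gives the replicate number of a column. After the data were seen, a fit without libraries E and G and a fit with each library's trend on GC content removed (lowess, span 0.3) were added. Counting precision does not limit the abundant genes at these depths, and any interval given covers counting error only.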

Results

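Gene expression was measured by RNA sequencing in whole gastrocnemius, a hindlimb muscle of mainly fast fibres, from control mice with a floxed glucocorticoid receptor gene (4 libraries) and from mice labelled as lacking the receptor in myofibres (4 libraries). The receptor, encoded by Nr3c1, is the nuclear receptor through which cortisol and corticosterone act on gene expression. Control libraries A, B, C and D held 36680510, 43403388, 41687630 and 44987629 counts, and libraries E, F, G and H, labelled knockout, held 37944368, 46638401, 40245606 and 52200305. In CPM of the library total, Xist was at most 0.15 and the Y-linked Kdm5d was at 13.2 to 16.5 in the 8 libraries. The Y-linked genes Uty and Ddx3y did not pass the edgeR test (adjusted p = 0.0562 and 0.0648). The single comparison of the design asks which transcripts differ in muscle when the receptor is deleted from its fibres.

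The targeted gene did not follow the label in 2 of the 4 libraries labelled knockout. Nr3c1 (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421, minus strand of mm10) was at 83.2, 89.6, 84.7 and 90.0 CPM in control libraries A, B, C and D. It was at 38.6 and 42.8 CPM in libraries F and H, respectively, but at 87.1 CPM in library E and 96.7 CPM in library G, also labelled knockout. The group means were 86.9 ± 3.43 CPM and 66.3 ± 29.8 CPM (SD, n = 4 each), a log2 fold change of -0.39 ± 0.31 (SE) that did not pass the edgeR test (adjusted p = 0.452) or the exact permutation test (p = 0.371, where the smallest possible p is 0.0286). Fkbp5, a co-chaperone of the receptor and a glucocorticoid-induced gene, was chosen for this comparison after its values were seen. It averaged 44.5 CPM in control and was at 32.2 CPM in library E, 6.68 in F, 31.4 in G and 10.7 in H (log2 fold change -1.15, edgeR adjusted p = 0.214, exact permutation p = 0.0286). Counts cover the whole gene, and the labels do not name the deleted part. Every direction below is therefore that of the libraries labelled knockout.

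**Figure D1:**
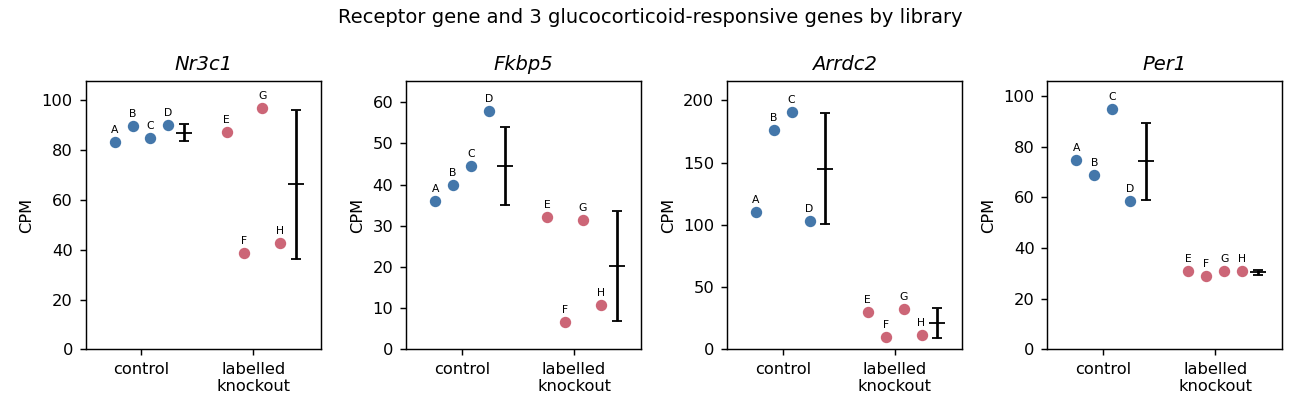
Expression in CPM (vertical axis) of Nr3c1, Fkbp5, Arrdc2 and Per1 in each control library (blue) and each library labelled knockout (red), with the group mean and SD in black (n = 4 each). Nr3c1 was at 87.1 and 96.7 CPM in libraries E and G, while Per1 averaged 30.5 CPM in the libraries labelled knockout against 74.1 CPM in control.

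Of 14712 genes tested, 1243 differed between the groups by the edgeR test, 594 higher and 649 lower in the libraries labelled knockout. The median size was 1.34-fold for genes that rose and 1.46-fold for genes that fell, and 211 genes differed at least 2-fold, 67 higher and 144 lower. In 1182 of these genes the 4 libraries of each group did not overlap, as did 2457 of all genes tested, where chance gives 2.86%. The count fell to 226 without libraries E and G, a choice made after seeing their Nr3c1, and to 683 when each library's trend on transcript GC content was removed. Without libraries E and G, 76 named genes lost their call, among them most of those named from the lists below. The count was 606, 1794, 612 and 890 without control libraries A, B, C and D, and 1184, 642, 373 and 699 without libraries E, F, G and H. It was 1963 by the DESeq2 Wald test and 1871 by limma-voom. Scaling by library size alone moved the share of higher calls from 47.8% to 69.8%.

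The largest falls included Arrdc2, an arrestin-domain gene induced by glucocorticoids, which fell from 145 ± 44.7 to 21.0 ± 12.0 CPM (log2 fold change -2.79 ± 0.49, edgeR adjusted p = 0.0208). It was at 30.2, 10.1, 32.6 and 11.2 CPM in libraries E, F, G and H. Prx, a Schwann cell protein, fell by 1.59 on the log2 scale. Slc25a25, a mitochondrial ATP-Mg/phosphate carrier, fell from 219 to 62.5 CPM, Sntb1, a syntrophin of the dystrophin complex, from 5.36 to 1.30 CPM, and Kif1a, an axonal transport motor, from 3.02 to 1.07 CPM. Syt12, Ctxn3, Mal and Fez1 fell by 1.66, 1.62, 1.63 and 1.61 on the log2 scale. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, went from 3372 ± 1803 to 230 ± 28.7 CPM (log2 fold change -3.87 ± 0.50, edgeR adjusted p = 0.00962). Lars2 took 0.306%, 0.404%, 0.484% and 0.102% of counts in control libraries A, B, C and D, where Gm42418, a transcript overlapping ribosomal RNA sequence and chosen after its values were seen, took 1.17%, 1.27%, 1.52% and 0.387%. In the libraries labelled knockout Lars2 took 0.021% to 0.0283% and Gm42418 0.0752% to 0.0978%. Both shares ranked the control libraries alike, highest in C and lowest in D. A fall of Lars2 mRNA therefore cannot be told apart from a fall of ribosomal RNA reads. Rpph1, the RNA component of ribonuclease P, went from 614 counts over the control libraries to 9 over the others, a ratio of 76.1 (95% exact interval 39.8 to 167, counting error only). That interval leaves out a wide spread between control libraries, with Rpph1 at 7.91, 2.89, 5.00 and 0.352 CPM in A, B, C and D. Its log2 fold change was -6.26 ± 1.10 (SE). When the GC trend was removed, the calls of Slc25a25 (log2 fold change -1.81 before and -1.80 after) and Fez1 (-1.61 and -1.52) ended with little change in size. Without libraries E and G those of Rpph1 (-6.26 and -6.26), Lars2 (-3.87 and -3.96), Mal (-1.63 and -1.77), Slc25a25 (-1.81 and -1.75) and Fez1 (-1.61 and -1.19) ended. Leaving out 1 library ended the calls of Arrdc2 (without C or H, highest adjusted p = 0.053), Rpph1 (F, G or H, 0.074), Fez1 (A, C, D, F or G, 0.0935) and Slc25a25 (any but D, 0.112).

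With predicted and unnamed genes skipped, the largest rise among the genes taken by the naming rule was that of Iigp1, an interferon-inducible GTPase, from 9.49 ± 2.42 to 92.9 ± 38.3 CPM (log2 fold change 3.29 ± 0.35, edgeR adjusted p = 0.00378). Ostn, which encodes the muscle secreted peptide musclin, rose from 15.3 ± 4.69 to 72.2 ± 46.5 CPM (2.24 ± 0.51, edgeR adjusted p = 0.0439). Dkk3, a secreted Dickkopf family protein, rose from 6.59 to 28.4 CPM, and Mib1, a ubiquitin ligase of the Notch pathway, from 58.3 to 176 CPM. The immunoglobulin heavy chain gene Ighg2c rose from 0.849 to 5.19 CPM, the mast cell carboxypeptidase gene Cpa3 from 1.18 to 3.37 CPM and the mitochondrial complex I gene mt-Nd6 from 32.0 to 104 CPM. For mt-Nd6, reads of the opposite strand cannot be told apart if strand was not used in counting. Nhs, Snx8, Cd209f and Cyp4f39 rose by log2 fold changes of 1.52, 1.46, 1.42 and 1.31. The call of Ostn ended when the GC trend was removed (log2 fold change 2.24 before and 1.99 after). Without libraries E and G those of Ighg2c (2.62 and 2.33), mt-Nd6 (1.70 and 1.82), Cpa3 (1.36 after), Snx8 (1.46 and 1.47), Cd209f (1.42 and 1.21) and Cyp4f39 (1.31 and 0.93) ended. Leaving out 1 library ended the calls of Cpa3 (G, adjusted p = 0.0521), Cyp4f39 (A, D, E, G or H, highest 0.0965), Ighg2c (any but B, 0.1) and Ostn (any but E, 0.11).

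The smallest p-values among rising genes belonged to Rasd2, a small GTPase, at 43.8 ± 3.49 against 118 ± 9.91 CPM (log2 fold change 1.43 ± 0.08, edgeR adjusted p = 1.67e-05), Ide, the insulin-degrading enzyme (1.09 ± 0.07), Btaf1 (1.22 ± 0.09), the muscle ubiquitin ligase subunit Asb15 (0.79 ± 0.07) and Rab4a (0.93 ± 0.08). Among falling genes they belonged to Mn1 (50.3 ± 5.21 against 21.6 ± 0.897 CPM, log2 fold change -1.22 ± 0.08, edgeR adjusted p = 3.61e-05), the inositol hexakisphosphate kinase gene Ip6k3 (-1.20 ± 0.08), the hypoxia-inducible factor gene Epas1 (-0.88 ± 0.07), Rmnd1 (-0.87 ± 0.07) and the pseudogene Eif3s6-ps4, which had 442 counts over the control libraries and 2 over the others, a ratio of 247 (95% exact interval 67.9 to 2040, counting error only). Each of these 10 genes passed with the GC trend removed, without libraries E and G, and with any 1 library left out. Ide and Btaf1 lie within 1 Mb of each other on chromosome 19. None of these fits tells an effect of the deletion from a linked genomic difference between the groups.

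**Figure D2:**
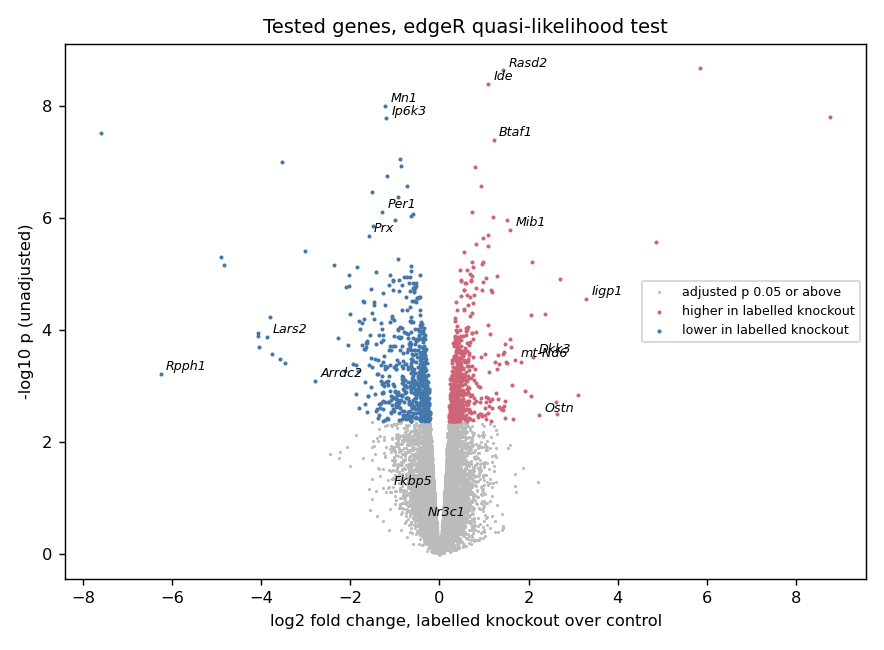
Log2 fold change, libraries labelled knockout over control (horizontal axis), against -log10 of the unadjusted edgeR p-value (vertical axis) for the 14712 genes tested. Red points are the 594 genes called higher and blue points the 649 called lower, and Nr3c1 and Fkbp5 lie among the grey genes that did not pass.

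The list of glucocorticoid-responsive genes passed camera as lower at the preset correlation (adjusted p = 4.8e-06), but not with an estimated correlation (adjusted p = 0.31), and had an adjusted p = 0.0188 by fry. Of 36 measured members, 7 fell, none rose and 29 did not pass, with a median log2 fold change of -0.35 (9 fell when adjusted over the list alone). Besides Arrdc2, whose call ended without C or H (highest adjusted p = 0.053), the clock gene and direct receptor target Per1 fell from 74.1 ± 15.3 to 30.5 ± 0.951 CPM (log2 fold change -1.28 ± 0.12, edgeR adjusted p = 0.000594). The glutamine synthetase gene Glul fell from 219 to 150 CPM and Hif3a from 1.55 to 0.578 CPM. The call of Hif3a ended with the GC trend removed (log2 fold change -1.43 before and -1.36 after), and those of Hif3a (-1.76) and Glul (-0.55 before and -0.73 after) without libraries E and G. So did those of Hif3a (any but B, highest adjusted p = 0.0908) and Glul (any but A or E, 0.082) with 1 library left out. The list of steroid receptors and corticosteroid metabolism genes did not pass camera (adjusted p = 0.191). In it 2 of 12 members rose: Hsd11b1, which regenerates active glucocorticoid, from 6.56 to 9.79 CPM, and the mineralocorticoid receptor gene Nr3c2 from 8.98 to 11.9 CPM (3 higher and 1 lower adjusted over the list alone). The call of Nr3c2 ended when the GC trend was removed (log2 fold change 0.40 before and 0.38 after), and both calls ended without libraries E and G (Nr3c2 0.50, Hsd11b1 0.57 before and 0.47 after). That of Nr3c2 ended without any 1 library but B or E (highest 0.103).

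In lists of energy metabolism genes most members did not pass the test. Among 35 glycolysis and glycogen genes, 12 fell and 1 rose (15 and 2 adjusted over the list alone), with a camera adjusted p = 3.92e-05 and an adjusted p = 0.31 with an estimated correlation. Gapdh fell from 2933 ± 183 to 2130 ± 171 CPM, the lactate transporter gene Slc16a3 from 355 to 234 CPM and the glycogen-targeting gene Ppp1r3c from 719 to 461 CPM. Its relative Ppp1r3a rose from 274 to 407 CPM, a call that ended when the GC trend was removed (log2 fold change 0.57 before and 0.27 after). Leaving out 1 library ended the calls of Ppp1r3c (C, F, G or H, highest adjusted p = 0.0739), Slc16a3 (any but B or E, 0.0686) and Ppp1r3a (any but E, 0.129). Among 78 nuclear-encoded respiratory chain genes, 5 fell and none rose (12 fell adjusted over the list alone). They had a median log2 fold change of -0.17, a camera adjusted p = 1.21e-07 and an adjusted p = 0.713 with an estimated correlation. Atp5g1 fell from 224 to 178 CPM, a call that ended without A, C, F or G (highest adjusted p = 0.0593). Its call stayed when the GC trend was removed. The calls of Cox8a (log2 fold change -0.43 before and -0.28 after), Ndufc2 (-0.35 and -0.35) and Ndufa8 (-0.28 and -0.17) in this list then ended. Cytosolic ribosomal protein genes had a median of -0.12 (camera adjusted p = 0.000987, adjusted p = 0.901 with an estimated correlation), with 1 of 76 called, Rpl29 (0 called adjusted over the list alone). The call of Rpl29 ended when the GC trend was removed (-0.29 before and -0.13 after) and without A, C, F, G or H (highest adjusted p = 0.0989). Fatty acid oxidation and lipid genes did not pass as a list (camera adjusted p = 0.971): 2 of 49 rose, among them the lipoprotein lipase gene Lpl, and 2 fell, among them Plin4 (2 and 2 adjusted over the list alone). The calls of Lpl (0.49 before and 0.36 after) and Plin4 (-0.50 and -0.38) ended when the GC trend was removed. They also ended with 1 library left out, Lpl without A, G or H (highest adjusted p = 0.072) and Plin4 without D, F or G (0.0752).

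Contractile and junction genes showed few single calls. Of 18 slow fibre genes, Myoz2 alone fell, from 123 ± 11.5 to 71.2 ± 14.5 CPM, with a list median log2 fold change of -0.49 (camera adjusted p = 0.00466, adjusted p = 0.713 with an estimated correlation, 1 lower adjusted over the list alone). The list had an adjusted p = 0.104 without control library D. Of 18 fast fibre genes, Mylpf and Casq1 fell (3 adjusted over the list alone), with a camera adjusted p = 0.0224 and an adjusted p = 0.713 with an estimated correlation. This became 0.227 with the GC trend removed, 0.0777 without libraries E and G, 0.186 without control library C and 0.0617 without library G. Of 23 denervation and neuromuscular junction genes, 4 fell, including Ncam1, Dok7 and the acetylcholine receptor subunit gene Chrne, and Hdac4 rose (4 and 1 adjusted over the list alone), with a camera adjusted p = 0.0224 and an adjusted p = 0.49 with an estimated correlation. The calls of Mylpf (log2 fold change -0.52 before and -0.44 after), Casq1 (-0.30 and -0.23), Chrne (-0.37 and -0.28) and Dok7 (-0.44 and -0.28) ended when the GC trend was removed. With 1 library left out, calls ended for Mylpf (A, C, G or H, highest adjusted p = 0.0788), Casq1 (any but D, 0.137), Chrne (C, D, G or H, 0.0755), Dok7 (any but B, 0.119) and Ncam1 (G, 0.0597). The junction list had an adjusted p = 0.203 with the GC trend removed, 0.107 without libraries E and G, 0.114 without control library B and 0.0507 without library E. Among 18 myogenic and regeneration genes, Ankrd1 and Mef2a rose and Myf6 fell (camera adjusted p = 0.971, 3 higher and 3 lower adjusted over the list alone). Of 31 calcium handling genes, 2 rose, among them Itpr1, and 4 fell, including Cacnb1 (camera adjusted p = 0.596, 2 and 4 adjusted over the list alone). The calls of Mef2a (0.41 before and 0.25 after) and Cacnb1 (-0.34 and -0.19) ended when the GC trend was removed. Those of Ankrd1 (adjusted p = 0.0552) and Myf6 (0.0648) ended without library G, and that of Cacnb1 without A, C, F, G or H (highest 0.095).

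Few genes of atrophy and protein turnover were called. Among 38 muscle atrophy genes, Bnip3l rose and Eif4ebp1 fell (camera adjusted p = 0.72, 0 adjusted over the list alone), and both calls ended when the GC trend was removed, with Bnip3l smaller (log2 fold change 0.37 before and 0.20 after) and Eif4ebp1 not (-0.65 and -0.66). None of 35 proteasome subunit genes was called by edgeR (3 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom, camera adjusted p = 0.678, 0 adjusted over the list alone), and the smallest p belonged to Psmc4, at 86.2 and 76.1 CPM. Of 41 autophagy genes, Bnip3l rose and Pik3c3 and Pik3r4 fell (camera adjusted p = 0.718, 3 higher and 3 lower adjusted over the list alone), and the call of Pik3r4 ended when the GC trend was removed (-0.27 before and -0.20 after). Among 46 insulin, IGF and mTOR signalling genes, 3 rose and 4 fell (camera adjusted p = 0.813, 3 and 5 adjusted over the list alone). Rictor, a subunit of mTOR complex 2, rose from 18.8 ± 1.69 to 31.3 ± 0.941 CPM and Igf2 went from 19.4 to 11.5 CPM, a call that ended when the GC trend was removed (-0.76 before and -0.65 after). Of 36 amino acid metabolism genes, 3 rose and 6 fell, among them the alanine aminotransferase gene Gpt2, from 409 to 276 CPM (camera adjusted p = 0.971, 5 and 6 adjusted over the list alone). In this list the calls of Prodh (-0.63 before and -0.55 after) and Slc7a8 (-0.59 and -0.50) ended when the GC trend was removed. Those of Gpt2 and Glul did not. Of 13 polyamine genes, Sms rose (camera adjusted p = 0.971, 0 adjusted over the list alone), a call that ended when the GC trend was removed (0.31 before and 0.18 after). Any 1 library but B or E, when left out, ended the calls of Eif4ebp1 (highest adjusted p = 0.135) and Bnip3l (0.105). The same held for Pik3c3 (C, G or H, 0.0819), Pik3r4 (any but B or H, 0.112), Igf2 (D, E, F, G or H, 0.0859), Gpt2 (C, F, G or H, 0.0664) and Sms (any but D or E, 0.126). The direction of the camera test was up while the median and mean log2 fold change lay below 0 for the insulin, amino acid and polyamine lists. For the circadian and the steroid receptor lists the median lay above 0 and the mean below it.

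Clock, stress and immune gene lists did not pass as lists, apart from immediate-early genes. Of 20 circadian clock genes, Rora and Hlf rose and Per1 and Usp2 fell (camera adjusted p = 0.988, 3 and 2 adjusted over the list alone), with the calls of Rora (log2 fold change 0.45 before and 0.26 after) and Hlf (0.42 and 0.33) ended when the GC trend was removed. Of 27 immediate-early genes, Atf3 (call ended with the GC trend removed, -1.04 before and -0.96 after), Nr4a3 and Nr4a1 fell (4 adjusted over the list alone), with a camera adjusted p = 0.0224 and an adjusted p = 0.901 with an estimated correlation. The list was at 0.12 with the GC trend removed, 0.141 without control library A, 0.0523 without control library B and 0.344 without library H. Of 42 interferon-stimulated genes, Iigp1 and Igtp rose (camera adjusted p = 0.402, 2 adjusted over the list alone). None of 32 inflammatory and NF-kappaB genes was called by edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone), with a camera adjusted p = 0.339 that became 0.0124 without control library A. Of 35 heat-shock and unfolded-protein genes, Hspb7 fell from 301 to 138 CPM and Hspa8 from 407 to 280 CPM (camera adjusted p = 0.718, 2 adjusted over the list alone). The processed pseudogene Gm15459, chosen after its values were seen, went from 0.187 to 81.7 CPM, and whether its reads come from Hspa8 was not measured. Of 31 cholesterol and fatty acid synthesis genes, Stard4 and Me1 rose (camera adjusted p = 0.411, 2 adjusted over the list alone). Calls that ended with 1 library left out were those of Hlf (any but D or E, highest adjusted p = 0.124), Atf3 (any but B or D, 0.0882), Nr4a3 (any but C or H, 0.102) and Igtp (any but B or E, 0.0877).

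Some markers of cells other than myofibres were called, in both directions. The 13 Schwann cell and nerve markers had a median log2 fold change of -1.29, and 11 fell, including Prx, Mag and Mal (13 adjusted over the list alone, camera adjusted p = 1.74e-21, adjusted p = 0.245 with an estimated correlation, adjusted p = 0.0135 by fry). Against the control mean, their median lay between -1.55 and -1 log2 units in the 4 libraries labelled knockout. Of 12 smooth muscle and pericyte markers, 6 fell, including Myh11, from 59.3 ± 5.37 to 31.1 ± 5.18 CPM, and Acta2, from 66.9 to 35.7 CPM (10 adjusted over the list alone, camera adjusted p = 4.93e-08, adjusted p = 0.245 with an estimated correlation). Of 18 endothelial markers, 8 fell, including Eng, and Cldn5 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.000243, adjusted p = 0.31 with an estimated correlation). Of 10 tenocyte markers, 4 fell, including Cilp2 and Col11a1 (5 adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.31 with an estimated correlation). Of 46 extracellular matrix genes, 8 fell and Dcn rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.000769, adjusted p = 0.901 with an estimated correlation), with Eln falling from 41.1 to 15.9 CPM and Col1a1 from 260 to 112 CPM. The matrix list had an adjusted p = 0.102 without libraries E and G and 0.0784 without control library B. The calls of Eln (log2 fold change -1.37 before and -1.23 after), Col1a1 (-1.22 and -1.07), Eng (-0.41 and -0.27) and Dcn (0.41 and 0.14) ended when the GC trend was removed. So did those of the tenocyte markers Fmod (-0.78 and -0.68) and Thbs4 (-0.69 and -0.58). The smooth muscle marker Cnn1 (-1.18 and -1.12) and the endothelial markers Sox18 (-0.71 and -0.54) and Robo4 (-0.38 and -0.27) lost their calls as well. With 1 library left out, calls ended for Eln (F or G, highest adjusted p = 0.066), Col1a1 (any but C or H, 0.135), Eng (G, 0.056), Col11a1 (G, 0.0601) and Cldn5 (any but B or H, 0.104).

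Macrophage markers had a median log2 fold change of 0.47 and 3 of 16 rose (Cd14, Adgre1 and Cd163; 4 adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.49 with an estimated correlation). Fibro-adipogenic progenitor markers had a median of 0.32 and 2 of 15 rose, Pi16 and Dcn (7 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.535 with an estimated correlation). The call of Dcn ended when the GC trend was removed. Leaving out 1 library ended the calls of Adgre1 (A, C, G or H, highest adjusted p = 0.0663), Cd163 (any but B or F, 0.0946), Pi16 (any but H, 0.123) and Cd14 (any but B or D, 0.0851). No member was called by edgeR among 5 neutrophil (camera adjusted p = 0.596), 9 lymphocyte (0.24), 11 adipocyte (0.229), 9 satellite cell (0.687) and 6 erythroid markers (0.485). Adjusted over the list alone, 1 satellite cell marker fell and 0 of the others were called. At an unadjusted p under 0.05 there was 1 satellite cell marker and 0 in the others, and DESeq2 called 1 satellite cell marker and limma-voom 0. Lymphocyte markers stood apart by library, with a median 3.11 log2 units above the control mean in control library A, 2.62 in library E and 2.78 in library G. They had a camera adjusted p = 0.000954 without control library A, 0.0122 without library F and 0.0104 without library H. Adipocyte markers had an adjusted p = 0.0314 without control library A and 0.00209 without control library B, and erythroid markers 0.00294 without library F.

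**Figure D3:**
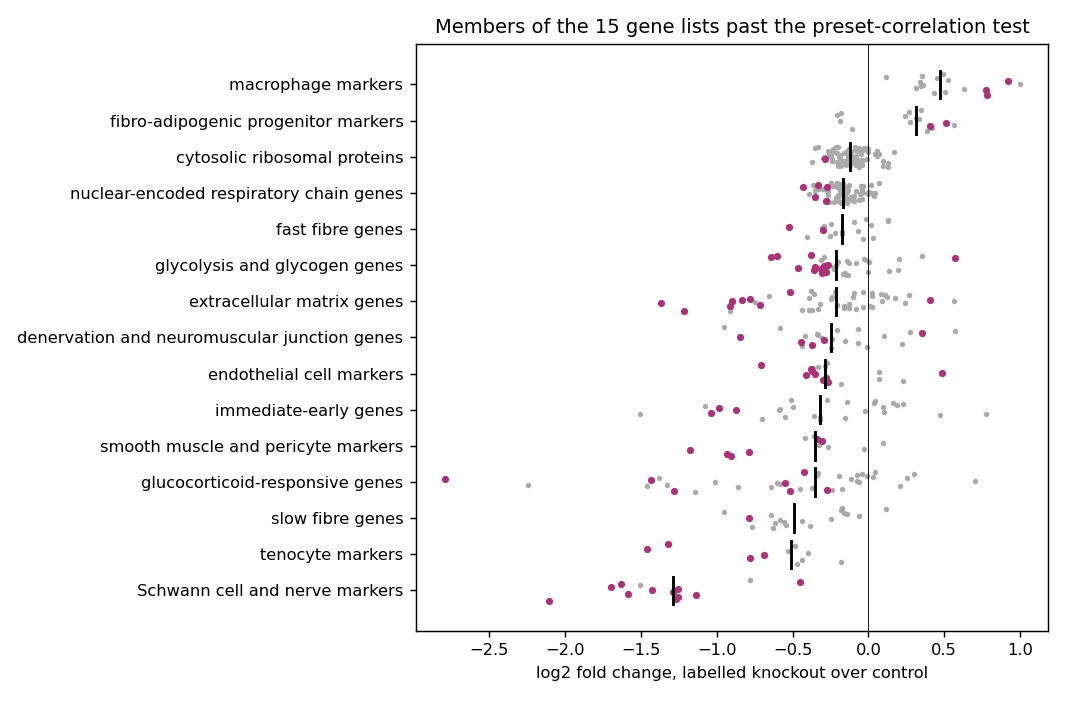
Log2 fold change, libraries labelled knockout over control (horizontal axis), of each measured member of the 15 lists that passed camera at the preset correlation. Purple points are members called over all genes, grey points are the others and black bars are list medians, which run from -1.29 for Schwann cell and nerve markers to 0.47 for macrophage markers.

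Of the 15 lists that passed camera, 13 lower and 2 higher, 0 passed with an estimated correlation (5 lists at an unadjusted p under 0.05) and 6 of the 35 passed fry, whose test of change in either direction called 28. Fold changes fell with transcript GC content across 14687 genes (Spearman correlation -0.447, over genes, which are not independent replicates). The median GC content was 43.5% for genes that rose, 54.2% for genes that fell and 49.7% for all tested. The trend differed between libraries of a group. The fitted difference between the highest and lowest GC decile was 0.404, -0.0045, 0.224 and 0.124 log2 units in control libraries A, B, C and D. It was 0.00149, -0.203, -0.225 and -0.349 in libraries E, F, G and H. In 10 of 35 splits of the 8 libraries at least 9 pathway lists passed camera, the count of the real split.

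**Figure D4:**
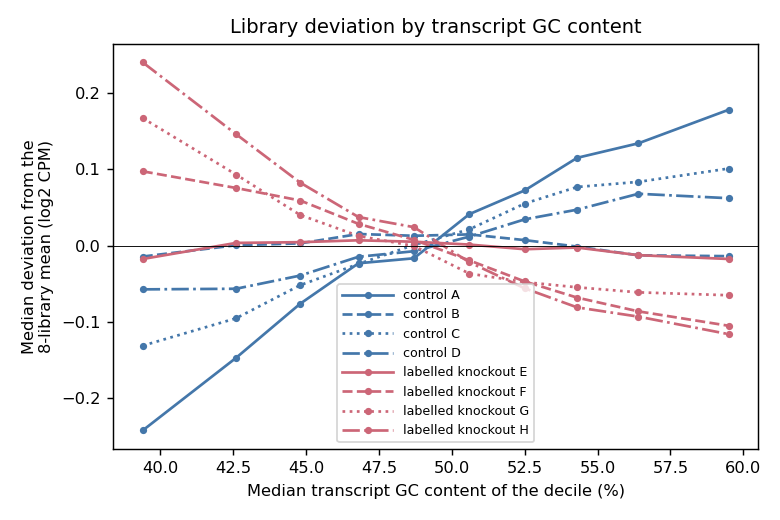
Median deviation of each library from the mean of the 8 libraries (log2 CPM, vertical axis) in deciles of tested genes by transcript GC content (percent, horizontal axis), with control libraries in blue and libraries labelled knockout in red. Control library B and library E are nearly flat, and control library A and library H have the steepest opposite slopes.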

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

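Of 260 sets of 4 values examined (each named gene and 5 library measures in each group), 22 had a highest or lowest library whose gap to the next was above Dixon's 95% critical share of the range. Chance gives about 13. Among control libraries, Mal was at 12.3 CPM in library B against 5.44 to 6.06 in the others, Robo4 at 26.4 CPM against 22.9 to 23.2 and Pnpla2 at 162 CPM against 201 to 208. Control library A had Snx8 at 6.26 CPM against 2.59 to 2.94 and Chrne at 18.4 CPM against 21.1 to 21.5. Control library D had Hif3a at 2.6 CPM against 1.07 to 1.31, Slc7a8 at 24.1 CPM against 14.4 to 15.9, Rora at 97.6 CPM against 83 to 84.1 and Rasd2 at 38.6 CPM against 45.3 to 46.

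Among libraries labelled knockout, H had the highest Fez1 (3.35 CPM against 1.01 to 1.23), Usp2 (114 CPM against 93.4 to 96.6), Eln (22.8 CPM against 13.2 to 14.1), Cilp2 (5.64 CPM against 3.53 to 3.6) and Thbs4 (102 CPM against 67.9 to 73.5). Library F had the highest Pik3c3 (17.4 CPM against 14.6 to 14.9), Igfbp3 (17.4 CPM against 12.8 to 13.4) and Lep (12.9 CPM against 2.07 to 3.8), and the lowest Per1 (29 CPM against 30.9 to 31.1) and Mag (0.338 CPM against 0.595 to 0.622). Library E had the highest Rab4a (17.4 CPM against 15.3 to 15.6) and Cacnb1 (166 CPM against 145 to 147), and library G the lowest Myf6 (60.4 CPM against 69.4 to 70.4).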

How the results depend on the processing

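The fits without libraries E and G and with the GC trend removed were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number of the labels. Without libraries E and G (fewer samples), 226 genes were called, 109 higher and 117 lower, 202 of them shared with the 1243. Nr3c1 was then at a log2 fold change of -1.09 (adjusted p = 0.00162), which is not independent evidence, since those libraries were left out for their Nr3c1. With the GC trend removed, 683 genes were called, 322 higher and 361 lower, and 558 were shared. The DESeq2 Wald test called 1963 genes, 1070 of them higher, and limma-voom 1871, 903 of them higher; library size alone called 936 higher and 405 lower (69.8% higher, against 47.8%) and shifted the median log2 fold change to 0.06. The cause was not tested for these. Requiring a 2-fold change left 211, 67 higher and 144 lower. Leaving out 1 library gave 373 to 1794 genes, 147 to 855 higher and 226 to 939 lower. The count was 606, 1794, 612, 890, 1184, 642, 373 and 699 without libraries A, B, C, D, E, F, G and H. Nr3c1 ran from -0.20 to -0.63, without a call, when 1 library was left out. Of 108 named genes called, 48 passed in each of these fits and 60 lost the call in at least 1.

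With an estimated correlation, 0 of the 9 pathway lists and 0 of the 6 marker lists passed, and fry called 2 pathway lists. No named gene or list changed direction while called in any setting run, and 1 of the 1243 had the opposite sign with the GC trend removed. Of the 108 named genes called, 40 lost their call with the GC trend removed and 76 without libraries E and G, against 4 with DESeq2 size factors, 1 with upper-quartile scaling, 7 with thinned counts, 19 with no filter and 20 with library size alone. Without library G, 59 lost it. The fit without libraries E and G has fewer samples, so a call lost there need not mean a smaller change. Gapdh was at -0.46 before and -0.45 after, and Fez1 at -1.61 and -1.19. With no filter, inflammatory genes (adjusted p = 0.0213), lymphocyte markers (0.0423) and adipocyte markers (0.00844) passed camera as well. Thinning to the smallest library left 1190 genes called.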

Other observations

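The tests of a swap, of library G alone, of library E alone, of each other cell type alike, of the GC trend as the whole cause, of other non-polyadenylated RNA and of processed pseudogenes were chosen after the result was seen, and the genes of the first paragraph, Gm42418, Gm15459 and Rmrp were chosen after their values were seen. Of the mitochondrial genome's genes, the 3 tested on the minus strand, mt-Nd6, mt-Tp and mt-Tq, were higher in the libraries labelled knockout, while 0 of 18 on the plus strand were called by edgeR (5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom); whether reads were counted by strand is not given. Ighg2c and Igha were higher (log2 fold change 2.62 ± 0.57 and 3.11 ± 0.69), and Ighm was at 132 and 234 CPM, which did not pass (adjusted p = 0.202). On chromosome 19, Fgfbp3, Btaf1 and Ide were higher by log2 fold changes of 1.15, 1.22 and 1.09, while Cpeb3 (0.11) and March5 (0.13), which lie between Btaf1 and Ide, were not called.

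Nr3c1 was near the control level in libraries E and G. A swap with control libraries would need a control library with low Nr3c1, and 0 were found, and more RNA from each other cell type alike would raise the markers of each, but for 10 of 11 types the median in E or in G was less than 1 log2 unit above the lower of F and H (the median of all markers, which go both ways, was at most -0.00328 above the control mean). A library of the control series under a knockout label is argued against for G, nearer the knockout mean for 98.4% of genes called without it, while for E that share, 67.1% (control libraries 10.7% to 41.5%), lay between the bounds set beforehand and left it undecided. For E the argument against it rests on a test chosen afterwards, in which its mean Spearman correlation was higher with the other libraries labelled knockout than with control libraries by 0.00588 (control libraries -0.00646 to -0.00277), whereas mean chi-square distances misplaced control library D (51.3 from libraries labelled knockout, 55.7 from control). A receptor lost in all 4 libraries with its RNA still counted may apply. All 4 carry the same label, so this alone does not explain why Nr3c1 was lower in F and H. Of 36 glucocorticoid-responsive genes, 16, 21, 15 and 13 lay below every control library in E, F, G and H (23% to 26.8% of all genes). The lower of E and G was 115% of the lower of F and H, although F had the most and these counts ignore the size of a fall. Fkbp5 differed between these pairs, as did Arrdc2 (30.2 and 32.6 CPM in E and G, 10.1 and 11.2 in F and H). Per1 did not (29.0 to 31.1 CPM in the 4 libraries). Incomplete or absent deletion in mice of the knockout series stays open. So does RNA from lymphocytes, whose markers were high in E and G but also in control library A with Nr3c1 at 83.2 CPM.

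Fold changes fell with GC content, and counts of Gm42418, a transcript overlapping ribosomal RNA sequence, differed between the groups. Counts of Lars2 differed too, and its share ranked the control libraries as that of Gm42418 did. Leaving out the 20 most abundant genes gave 1246 calls, 1230 of them shared, within the bound set beforehand. TMM gives extreme genes little weight, so this test could hardly have come out otherwise. It therefore does not decide whether a few abundant genes set the scale. Library size alone did move the share of higher calls, to 69.8%. A GC trend may have produced many calls: after its removal 44.9% of the genes changed stayed called, and the 685 lost had a median absolute log2 fold change of 0.378 before and 0.24 after at a median SE of 0.0901 and 0.0809, with a smaller change in 669 of them and one as large or larger in 16; 67 kept at least 0.9 of it, so a smaller change ended many of these calls but not each. The trend as fitted does not account for every call. With it removed, 558 genes stayed called in the same direction, with a median absolute log2 fold change of 0.649 before and 0.589 after. A GC effect that this fit left in place was not tested. Whether the trend comes from library preparation or from genotype stays open, since no batch is labelled, and so does a carry-over of non-polyadenylated RNA, since 22 genes of other such classes had a median log2 fold change of 0.148, and the 2 ribozyme RNAs among them, Rpph1 and Rmrp, were lower (-6.26 and -4.84).

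Some genes were nearly absent in 1 group and present throughout the other. For Gm15459, reads exchanged with Hspa8 may account for it, since Hspa8 lost 127 ± 20.7 CPM (SE) where Gm15459 gained 81.5 ± 13, or 156% of the gain. A difference in read alignment may also contribute among genes that fell, with a median log2 fold change of -0.424 over 231 processed pseudogenes, outside the -0.06 to 0.07 that held 95% of 10000 random lists matched on expression. Of these pseudogenes 22 were called lower and 4 higher, so the class shifted opposite to the rise of Gm15459. Linked genomic differences between the groups are a candidate explanation as well, since 128 of 211 genes changed at least 2-fold had a called neighbour of the same direction within 1 Mb, against 107 on average for matched genes (permutation p = 0.0014, one-sided), though neighbours regulated together would give this too. Random genes for the pseudogenes and for the neighbours were matched on expression and not on GC content, with which fold changes fell. Neither test therefore separates its explanation from the GC trend. The 3 explanations and an effect of genotype stay open.

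Among the 35 splits of the 8 libraries into 4 and 4, only the real split gave as many as 1243 genes, 594 higher or 649 lower. The highest count of another split was 11. This argues against a chance division for these counts, at the smallest share that 35 splits allow (1 of 35). The splits do not separate genotype from the GC trend or from an unlabelled batch. For the lists chance cannot be excluded: 10 of 35 splits gave at least 9 pathway lists (highest other 11) and 14 gave at least 6 marker lists (highest other 9).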
